A study of Mus musculus with 4 samples.

How the data were processed

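RNA from cultured mouse microglia, the resident macrophages of the brain, was measured on 4 Affymetrix Mouse Gene 1.0 ST arrays, which read many probes along each transcript. The labels give 1 array to each of 4 groups: wild type (WT) without treatment, WT with lipopolysaccharide (LPS) for 3 h, Bid–/– without treatment, and Bid–/– with LPS for 3 h. The design text states that nothing was replicated. The strain is labelled for the WT arrays, as C57Bl. For the arrays labelled Bid–/– the background, the sex of the animals and the number of cultures are not given in the sources used here.

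The authors deposited 1 table with a value for each of 28944 probe sets on each array. Robust multi-array average (RMA), Affymetrix Expression Console and Partek 6.2 are named per the submitters' processing notes, with no role or order. The deposited values were taken as log2 expression: they have 2 decimals, run from 1.4 to 13.5, and have medians of 4.25 (WT control), 4.28 (WT LPS), 4.24 (labelled Bid–/– control) and 4.25 (labelled Bid–/– LPS). The log base is not written in the file, so every fold below rests on that reading. RMA brings the arrays to a common distribution, so a shift shared by all genes would be removed before any comparison. Scanner values and the probe-level background were not used here, and the number of arrays limits the precision.

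Genes were named from the platform annotation supplied with the series. It gave 1 gene symbol to 21789 probe sets, several to 1621 and none to 5534; no gene was named from the last 2 kinds. Of the probe sets with 1 symbol, 21698 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names, gene order and gene span alone. For 999 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was used, leaving 19938 genes. A gene entered a comparison when the higher of the arrays compared reached a floor of 4.26, the median over all probe sets of the mean of the 4 arrays. Counts are of genes with an at least 2-fold difference. With 1 array per group, a difference between 2 arrays has no replicate check and was given no p-value.

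The additive model, log2 expression on genotype and LPS, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, Benjamini-Hochberg adjustment, threshold 0.05) on 11326 genes. It asks whether a change was seen in both genotypes or both conditions. The error comes from the difference of response between genotypes, with 1 residual degree of freedom. A gene whose LPS response truly differs between genotypes is therefore penalised. Nothing in the labels says whether the arrays of a genotype came from separate cultures, so the rest of the spread behind these p-values may be technical. Because the values are rounded, 169 genes had a residual of exactly 0, which lowers the prior degrees of freedom to 3.07 and the number of calls. The fit was tested on simulated data for 11326 genes with 200 genes changed: it recovered 34.8% of changes of 1 on the log2 scale, 76.8% of 1.5 and 95% of 2, and 7.68% of its calls were false. The simulated values were not rounded and each change was equal in both genotypes. These rates therefore do not carry over to the fit of the real values.

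The gene lists, named genes, comparisons, models and most alternatives were fixed before the data were examined. There were 28 lists with 482 genes, of which 439 had a value. The LPS response lists were cytokines, chemokines, NF-kB feedback, immediate early and MAPK feedback, interferon-stimulated, and inflammatory enzymes and effectors. The pathway lists were TLR4 pathway components, the Bcl-2 family, death receptors and caspases, inflammasome and pattern receptors, MHC class I presentation, MHC class II and costimulation, phagocytosis and lysosome, cell cycle, cholesterol synthesis, and heat shock and ER stress. Cell type lists covered homeostatic microglia, astrocytes, oligodendrocyte lineage, neurons, fibroblast and mural cells, endothelium, monocytes and border macrophages, neutrophils, and lymphocytes. Controls were sex-linked, strain-variable and housekeeping genes. Each list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins; this describes these arrays and is not a test. In simulated data with genes independent of each other, 6 of 100 unchanged lists and 87 of 100 moved lists fell outside the middle 95% of random lists. Members of a real list can move together, so a larger share of real lists can fall outside without a common cause.

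Named genes were Bid and its 10 neighbours on each side, the 15 highest and 10 lowest LPS changes among genes at least 2-fold in both genotypes, the 10 highest and 10 lowest genotype differences among genes at least 1.5-fold in both conditions, the 10 highest and 10 lowest signed differences of LPS change among genes at least 2-fold in either genotype, up to 4 members of each list with the largest values, and Tnf, Il1b, Il6, Nos2, Ptgs2, Tlr4 and Cd14. Symbols of predicted genes were counted and not named. A set of 24 further fibroblast transcripts was chosen after the fibroblast and mural result was seen. Other members of a list that are named were chosen after the values were seen.

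Alternatives were quantile normalization, removal of an intensity trend from each difference, no floor, a floor at the 75th percentile (6.34), a 1.5-fold threshold, the mean over a gene's probe sets, a fit without an intensity trend, a fit without the other factor, lists limited to genes above the floor, and random lists matched on the mean response as well. Noise within the rounding (0.005 either way, 3 draws) and removal of a trend with gene span were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.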

Results

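The series asks how the inflammatory expression profile of microglia depends on Bid, a BH3-only protein of the Bcl-2 family that carries death receptor signals to mitochondria. Microglia labelled WT or Bid–/– were left untreated or given LPS, a bacterial cell wall component recognised by TLR4, for 3 h. Each of the 4 groups was measured on 1 array, so no difference between 2 arrays has a replicate check. Across 28944 probe sets, Pearson's r between arrays ran from 0.984 to 0.996. The 2 untreated arrays were the most alike (r 0.996, SD of the difference 0.19), ahead of the 2 LPS arrays (r 0.990, SD 0.31).

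Bid itself was slightly lower on the control array labelled Bid–/– and higher on the LPS array so labelled. Its single probe set read 5.69 on the WT control array and 5.53 on the control array labelled Bid–/–, a difference of -0.16 on the log2 scale. With LPS it read 5.02 in WT and 5.97 on the array labelled Bid–/–, 0.95 higher. Where the probes lie against the deleted part of the gene is not given in the sources used here, so the probe set may check nothing; genotypes below are those of the labels, and every direction between genotypes rests on those labels. Among the 10 measured protein-coding neighbours on each side of Bid, the next gene before it, Bcl2l13, differed by 0.13 without and 0.03 with LPS, and the next after it, Mical3, by -0.18 and 0.24. The neighbour with the largest difference with LPS was Atp6v1e1, a proton pump subunit, at -0.28 without and -0.76 with LPS. Differences with LPS of 0.57 were read for Kdm5a and 0.54 for Slc6a12. The Y-linked genes Eif2s3y, Kdm5d and Uty were higher on both arrays labelled Bid–/–, by 1.00, 0.63 and 0.91 without LPS and by 0.95, 0.92 and 1.61 with it. Xist, transcribed from the inactive X chromosome, read 8.05, 8.24, 7.73 and 8.27 on the WT control, WT LPS and labelled Bid–/– control and LPS arrays. Nnt, a mitochondrial transhydrogenase that varies between C57BL/6 substrains, was lower on both arrays labelled Bid–/– (-0.81 and -0.79). A difference in sex, background or culture therefore cannot be told apart from an effect of Bid in any comparison between the labels below.

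**Figure D1:**
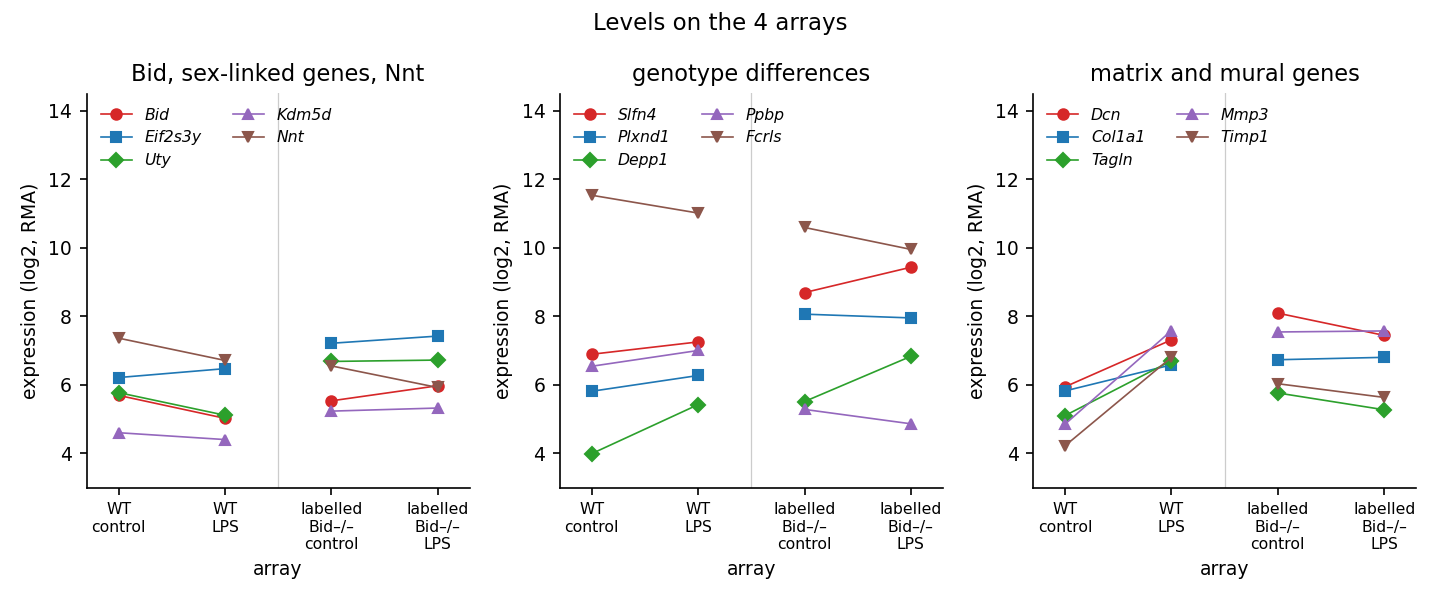
Log2 expression (RMA, vertical axis) of 15 genes on the 4 arrays (horizontal axis), 1 point per array, lines joining control and LPS within a genotype label. Bid reads 5.53 and 5.97 on the arrays labelled Bid–/– against 5.69 and 5.02 in WT, Slfn4 and Plxnd1 are higher there in both conditions, and Dcn is lowest on the WT control array at 5.94.

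LPS gave a classical inflammatory response in cells of both labels. Il6, the cytokine interleukin-6, rose by 4.47 on the log2 scale in WT and 3.68 on the arrays labelled Bid–/– (SE of the mean change 0.24, limma adjusted p = 0.0225). Edn1, the endothelin-1 precursor, rose by 3.48 and 4.29 and Tnfsf15, a TNF family ligand, by 3.80 and 3.72. The growth and differentiation factors Lif (3.85 and 3.41), Csf2 (4.01 and 3.18) and Csf3 (3.63 and 2.62) rose, as did the neutrophil-attracting chemokines Cxcl1 (4.20 and 2.96) and Cxcl2 (3.46 and 2.83). Il1a (3.77 and 2.63), Il12b, which encodes the p40 subunit (3.72 and 2.86), the protease inhibitor Serpinb2 (3.91 and 2.61), the arginine transporter Slc7a2 (3.57 and 3.65), the inflammasome sensor Nlrp3 (3.16 and 3.26), the histone demethylase Kdm6b (3.10 and 3.02) and the NF-kB signalling paracaspase Malt1 (2.99 and 3.11) complete the 15 highest. Among the genes that fell most were Sesn1, a stress-responsive sestrin (-2.52 and -2.47), Nrros (-2.33 and -2.32), Tmem140 (from 7.43 to 4.84 and from 7.86 to 5.86), the AMPK-related kinase Nuak1 (-2.29 and -2.25), Tmem86a (-2.36 and -2.06), the peroxisomal transporter Abcd2 (-2.32 and -2.04), Rab3il1 (-2.19 and -2.16), the prostaglandin E receptor Ptger4 (-2.06 and -2.16), the lysophosphatidic acid receptor Lpar6 (-1.89 and -2.32) and the transcription factor Bhlhe41 (-1.53 and -2.43). For these 25 genes the limma adjusted p lay between 0.0208 and 0.045.

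In WT, 266 of 11129 genes were at least 2-fold higher and 231 at least 2-fold lower with LPS. On the arrays labelled Bid–/–, 297 of 10995 were higher and 181 lower, so that 62.1% of these genes were higher; after removal of an intensity trend this share was 77.9% (395 higher, 112 lower). Of 11326 genes that reached the floor on any of the 4 arrays, 187 were at least 2-fold higher in both genotypes, where independent lists would share 7.0, and 106 were lower in both against 3.7. No gene (0) was 2-fold changed in opposite directions. Across 11326 genes, which are not independent replicates, the responses in the 2 genotypes had r = 0.744 and rho = 0.601, and the total least squares slope of the response labelled Bid–/– on the WT response was 0.969. The additive limma fit called 190 genes higher and 177 lower with LPS. That total of 367 moved from 0 without a floor to 2184 with noise inside the rounding of the values.

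**Figure D2:**
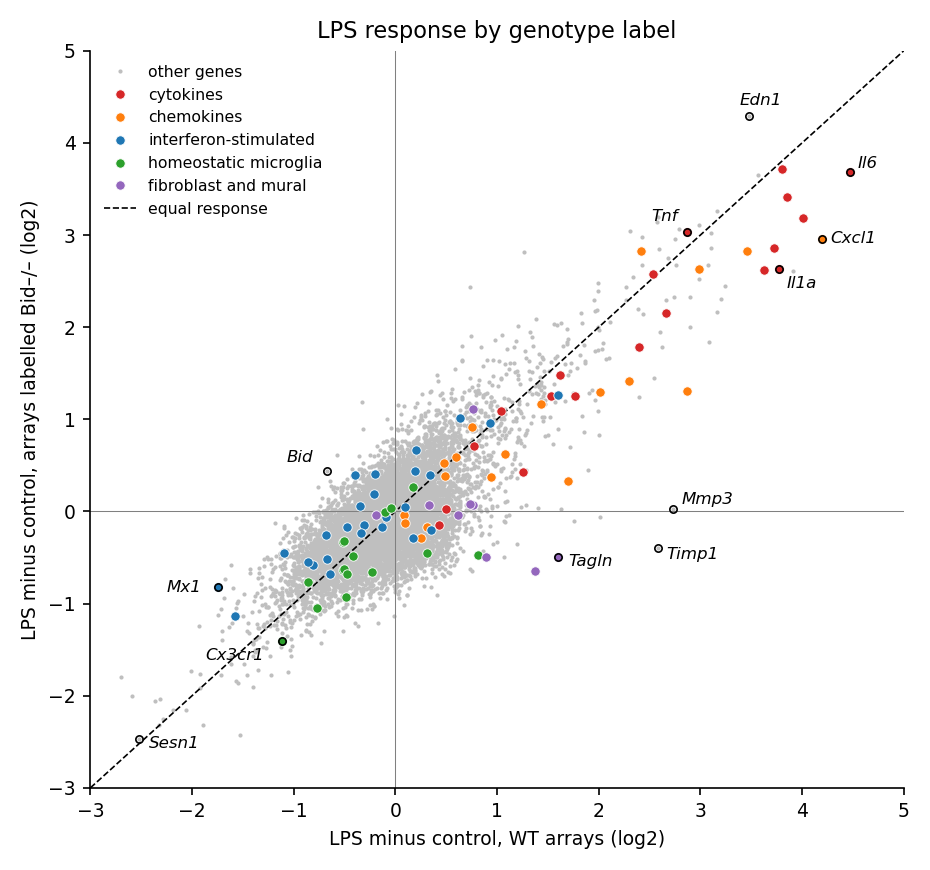
LPS minus control (log2) on the WT arrays (horizontal) against the arrays labelled Bid–/– (vertical), 1 point per gene above the floor, with members of 5 gene lists in colour and the line of equal response dashed. Il6 lies at 4.47 and 3.68, Tnf at 2.87 and 3.03, Sesn1 at -2.52 and -2.47, while Mmp3 (2.73 and 0.03) and Tagln (1.60 and -0.49) lie near or below 0 on the vertical axis.

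Of 19 cytokines tested, 15 rose over all genes tested and 17 when adjusted over the list alone, with Tnf at 2.87 in WT and 3.03 on the arrays labelled Bid–/– and Il1b at 1.77 and 1.25 (limma adjusted p = 0.0208 and 0.0401). Of 19 chemokines 7 rose, 14 when adjusted over the list alone, among them Ccl4 (2.42 and 2.83), Ccrl2 (2.99 and 2.63) and Cxcl10 (2.01 and 1.30). Without regard to the fit, all 19 were above 0 with LPS in WT and 15 on the arrays labelled Bid–/–. The fit penalises genes whose responses differ, such as Cxcl3 (2.87 and 1.31), which did not pass. Of 19 NF-kB feedback genes 11 rose, 16 when adjusted over the list alone, including Tnfaip3, which encodes the deubiquitinase A20 (2.43 and 2.68), and Nfkbia, which encodes IkBa (1.46 and 1.29). Of 22 immediate early and MAPK feedback genes 8 rose, or 16 with 2 that fell when adjusted over the list alone; Maff (3.24 and 2.45) and the phosphatases Dusp1 (2.27 and 2.29) and Dusp16 (1.99 and 2.39) were among the 8. Of 26 inflammatory enzymes and effectors 10 rose, or 14 with 1 that fell when adjusted over the list alone; these included Ptgs2, the inducible cyclooxygenase (2.90 and 2.00), and the collagenase Mmp13 (2.99 and 2.52). Nos2, the inducible nitric oxide synthase, was 1.21 and 0.81 higher with LPS and did not pass (limma adjusted p = 0.0594).

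Among interferon-stimulated genes few passed for LPS. Of 26 tested, 2 rose (Gbp5, 1.60 and 1.26; Oasl1, 0.93 and 0.96) and 1 fell (Iigp1, an interferon-inducible GTPase, -1.58 and -1.14); adjusted over the list alone, 3 rose and 6 fell. Ifit1 read 10.21 on the WT control array before any LPS, and Mx1, an antiviral GTPase, was -1.75 in WT and -0.82 on the arrays labelled Bid–/–. The list median was -0.21 in WT (percentile 1.90, 17 of 27 below 0); on the arrays labelled Bid–/– it was -0.15 and turned to 0.01 after removal of an intensity trend. Homeostatic microglia markers were lower with LPS as a list, with medians of -0.42 and -0.47 against random medians from -0.23 to 0.14 and from -0.26 to 0.11. Of 16 tested, 0 rose and 1 fell, Cx3cr1, the fractalkine receptor (-1.12 and -1.41, limma adjusted p = 0.045); 10 fell when adjusted over the list alone. P2ry13 read -0.77 and -1.05 and Mef2c -0.86 and -0.77. Among TLR4 pathway components none passed (0 of 24, with 5 that rose and 2 that fell when adjusted over the list alone). As a list they were higher with LPS, with medians of 0.23 in WT and 0.34 on the arrays labelled Bid–/– (percentiles 99.9 and 100.0). Of 24 genes 16 and 18 were above 0. Tlr4 itself read -0.92 and -0.81, Rela 1.08 and 0.80, and the co-receptor Cd14 0.38 and 0.46.

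Without LPS, the array labelled Bid–/– read many inflammatory genes higher than the WT control array. The cytokine list had a median difference of 0.33 (random lists -0.08 to 0.10), with Il1a 1.31 and Il1rn 0.81 higher; 6 of 20 were below 0, among them Il10 (-0.49) and Tnf (-0.30). The chemokine median was 0.34 (Cxcl5 1.18 and Cxcl3 1.00 higher; 5 of 19 below 0, among them Ccl4 at -0.63), and that of inflammatory enzymes and effectors 0.34 (Mmp3, stromelysin-1, 2.69 higher, Serpinb2 1.55, Nos2 1.22, Ptgs2 1.16, but Mmp9 -0.95). All 3 medians lay at percentile 100.0 of random lists. Of 27 interferon-stimulated genes, 26 were above 0, with a median of 0.27. Fibroblast and mural genes moved with these groups: their median was 0.52 (percentile 100.0), with Dcn, the matrix proteoglycan decorin, 2.15 higher and Col1a1, a collagen I chain, 0.91 higher. In all, 39 of 10909 genes were at least 2-fold higher and 8 at least 2-fold lower on the array labelled Bid–/–, a comparison of 2 arrays with no test.

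With LPS, interferon-stimulated genes were higher on the array labelled Bid–/– than on the WT array. The interferon-stimulated median was 0.52 higher on the array labelled Bid–/– (percentile 100.0), 23 of 27 genes were above 0, and Mx1 (1.38), Iigp1 (1.32) and Mx2 (1.07) were at least 2-fold higher. Cytokines had a median of -0.10 and chemokines of -0.15, both within the random lists and both turning to 0.03 and 0.02 once trends with intensity and gene span were removed; Csf3 (-0.93), Csf2 (-0.87) and Cxcl1 (-0.75) were lower and Il1rn (0.67) and Tnfsf15 (0.63) higher. Inflammatory enzymes and effectors had a median of 0.115 and NF-kB feedback genes of 0.17, both within the random lists, or 0.28 and 0.25 once both trends were removed. Immediate early and MAPK feedback genes were lower, with a median of -0.18 (percentile 0.99), which shrank to -0.055 once trends with intensity and gene span were removed, and of -0.10 without LPS (percentile 0.42). In all, 36 of 11044 genes were at least 2-fold higher and 54 lower, 40.0% higher. That share was 53.4% after quantile normalization and between 37.4% and 44.0% in the other settings. Ribosomal protein genes (64, median -0.52) and oxidative phosphorylation subunits (72, median -0.71) were lower on the array labelled Bid–/–, with 58 and 69 genes below 0; these families were chosen after their values were seen. The difference between the 2 LPS arrays followed gene span (Spearman rho 0.399 across 11017 genes, 0.138 without LPS). Of 10 equal bins by span, the shortest had a median of -0.18 and the longest of 0.21. With trends in intensity and gene span removed, the family medians were -0.35 (ribosomal protein) and -0.645 (oxidative phosphorylation).

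**Figure D3:**
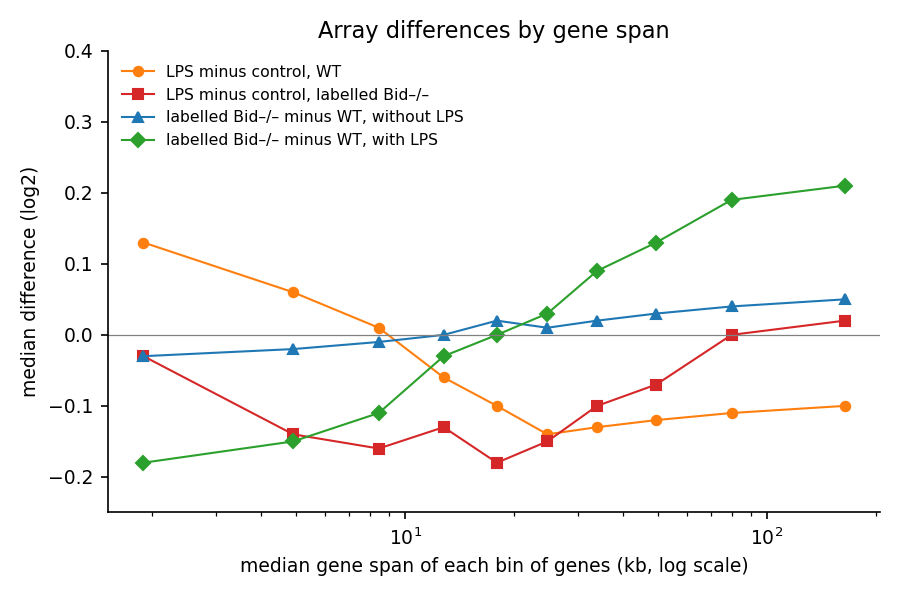
Median log2 difference (vertical axis) in 10 equal bins of genes ordered by gene span, against the median gene span of each bin (kb, log scale), for the 4 comparisons of 2 arrays. The difference between the LPS arrays runs from -0.18 in the shortest to 0.21 in the longest genes, and that between the control arrays from -0.03 to 0.05.

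Some genes differed between the genotype labels in both conditions. Slfn4, an interferon-responsive schlafen gene, was 1.80 higher without and 2.18 higher with LPS on the arrays labelled Bid–/–, Plxnd1, a semaphorin receptor, 2.25 and 1.68, and Depp1 1.52 and 1.41. Plxnd1, Depp1 and, among the lower genes, Clec4a2 lie 50, 37 and 29 protein-coding genes from Bid. For these genes a difference of that genomic region is a further source that cannot be told apart from an effect of Bid. For all genes in this part, sex, background and culture cannot be told apart from it either. Uty, the matrix glycoprotein gene Tnc (1.54 and 0.88), Cfb, complement factor B (1.27 and 1.08), Adgb (0.74 and 1.59), Iigp1 (0.88 and 1.32), Thbs1, thrombospondin-1 (1.14 and 0.97), and Nos2 (1.22 and 0.82) were also higher. Lower on both were the chemokine Ppbp (-1.26 and -2.14), the 5S ribosomal RNA gene n-R5s136 (-0.65 and -2.25), the C-type lectins Cd209f (-1.28 and -1.11) and Clec4a2 (-0.86 and -1.25), Wfdc17 (-0.88 and -1.39), the microglial receptor Fcrls (-0.94 and -1.06), Morc4 (-1.04 and -0.93), Cd5l, a protein secreted by macrophages (-1.16 and -0.81), Ndrg1 (-1.06 and -0.88) and the potassium channel Kcnn4 (-0.98 and -0.92). Of 10234 genes with given names, 45 were at least 1.5-fold higher in both conditions, where independent lists would share 7.0, and 21 lower in both against 2.6; 4 went in opposite directions. The additive limma fit called 0 of 11326 genes for genotype, and 20 after quantile normalization. An unadjusted limma p under 0.05 was read for 709 genes, where a share of 0.05 of the genes tested would lie there without any effect. The labels do not say whether a genotype was more than 1 culture.

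**Figure D4:**
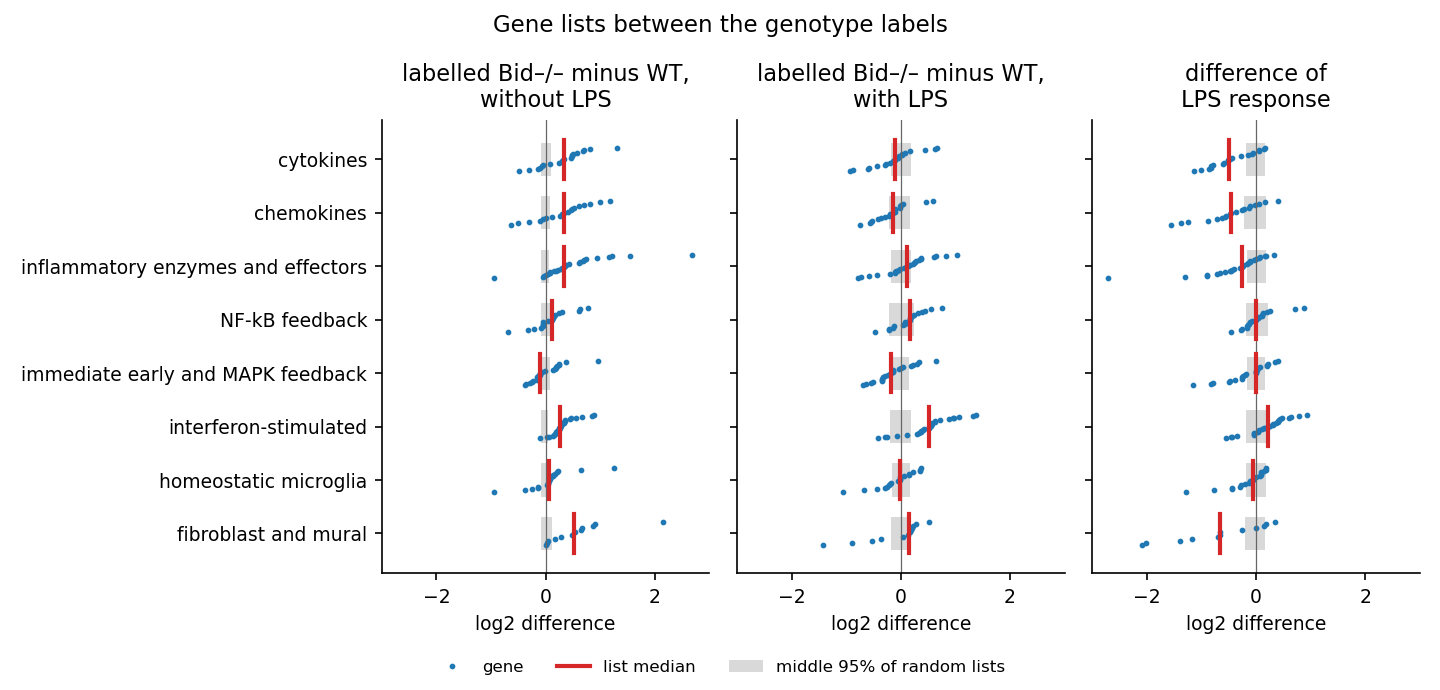
Log2 differences (horizontal axes) of the members of 8 gene lists (rows of points, 1 per gene) between the genotype labels without LPS, with LPS, and in the LPS response; red lines are list medians and grey bars the middle 95% of random list medians. Cytokine medians are 0.33, -0.10 and -0.49, interferon-stimulated medians 0.27, 0.52 and 0.23, and fibroblast and mural medians 0.52, 0.15 and -0.66.

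The LPS response of inflammatory genes was smaller on the arrays labelled Bid–/– for many list members. Of 53 genes on the 6 response lists that rose in the additive fit, 36 responded less, 16 more and 1 equally, with a median difference of -0.27 (-0.14 once trends with intensity and gene span were removed). These genes started higher on the control array labelled Bid–/– (median 0.31) and had a median difference of -0.01 with LPS, or of 0.13 once the same trends were removed. The fit that chose them penalises genes whose responses differ. Of 55 response-list genes at least 2-fold higher with LPS in both genotypes, 39 responded less and 15 more, with a median difference of -0.30. The median difference of response was -0.49 for cytokines and -0.46 for chemokines, both at percentile 0.0 of random lists; with both trends removed they were -0.31 and -0.23. It was -0.25 for inflammatory enzymes and effectors (percentile 0.35) and -0.06 after removal of an intensity trend. That removal raised the median of all 11326 genes from 0.0 to 0.077, so list values in that setting are not to be read against 0. The median difference of response was 0.00 for NF-kB feedback, 0.01 for immediate early and MAPK feedback genes, and 0.23 for interferon-stimulated genes (percentile 99.7). The last was 0.44 after removal of an intensity trend. Other groups moved the same way: the difference of response was -0.66 for fibroblast and mural genes, -0.475 for ribosomal protein genes and -0.595 for oxidative phosphorylation genes. With trends in intensity and gene span removed these were -0.61, -0.19 and -0.42. Among single genes, several of them stromal, the LPS change on the arrays labelled Bid–/– minus that in WT was lowest for Timp1, a metalloproteinase inhibitor (-2.98), Mmp3 (-2.70), the smooth muscle gene Tagln (-2.09), the U3 small nucleolar RNA Rnu3a (-2.07), Dcn (-2.02), the Wnt antagonist Sfrp4 (-1.86), n-R5s136 (-1.60), S100a6 (-1.57), Cxcl3 (-1.56) and the matricellular gene Ccn2 (-1.55). It was highest for Phxr4 (1.56), the microRNA genes Mir181b-1 (1.16), Mir125a (1.12) and Mir181a-1 (1.06), Capns2 (1.15), Snora30 (1.08), H2-M2 (1.07), Styx (1.05), the iron exporter Slc40a1 (1.04) and Tbrg3 (1.01). For Styx (-1.18 in WT and -0.13 on the arrays labelled Bid–/–) and Slc40a1 (-1.62 and -0.58) the positive value is a smaller decrease. In all, the LPS change was at least 2-fold higher for 18 of 11326 genes and at least 2-fold lower for 71, 20.2% higher, against 45.2% after removal of an intensity trend. With 4 arrays the difference of response was not tested, and it shares the control arrays with the comparison without LPS.

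Fibroblast and mural genes had a median LPS difference of 0.70 in WT (percentile 100.0) and 0.02 on the arrays labelled Bid–/–, and a difference of response of -0.66 (percentile 0.0). Acta2, smooth muscle actin, read 6.26, 7.15, 6.75 and 6.25 on the WT control, WT LPS, and labelled Bid–/– control and LPS arrays. The floor was reached on some array by 2 of 12 neuron, 1 of 10 neutrophil and 2 of 9 lymphocyte genes, and by 9 of 13 astrocyte, 9 of 12 oligodendrocyte lineage, 5 of 10 endothelial, and 4 of 10 monocyte and border macrophage genes. Median differences between genotype labels without LPS were 0.07, -0.04 and -0.03 for neuron, neutrophil and lymphocyte genes, and those of astrocyte, oligodendrocyte lineage, endothelial, and monocyte and border macrophage genes 0.00, 0.14, 0.08 and -0.01, the last changing sign after quantile normalization. The oligodendrocyte lineage median was at percentile 99.5, with Pdgfra, which fibroblasts also express, 0.99 higher. Pf4, a border macrophage marker that read 9.23 on the WT control array, was -0.48 without and -1.47 with LPS. Sex-linked, strain-variable and housekeeping lists had medians of 0.77, 0.02 and -0.02 without LPS and 0.94, 0.17 and 0.03 with it. Once an intensity trend was removed, the housekeeping median without LPS changed sign and that with LPS was 0.19.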

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

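All tests in this part were chosen after the results were seen. Single genes stood out because their LPS change had opposite signs in the 2 genotype labels, or because the difference between labels had opposite signs with and without LPS; probe sets outside the comparisons stood out because they gave signal. None of these differences was tested, since each rests on 1 array per group.

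Bid was 0.67 lower with LPS in WT and 0.44 higher on the arrays labelled Bid–/–, a difference of response of 1.11; between labels it was 0.95 higher with LPS. Exchanged genotype labels on the 2 LPS arrays are argued against: of 189 genes at least 1.5-fold different between labels without LPS, leaving out predicted genes and genes below the floor in either condition, 145 (76.7%) differed in the same direction with LPS. The exact 95% interval of 70.0 to 82.5 treats genes as independent, which they are not, so it does not measure doubt about the labels. Both label differences rise with gene span, which can raise such agreement. Across 11326 genes r between them was 0.332, and 0.32 with trends in intensity and gene span removed from each. A probe set that reads transcript left by the deletion stays open, since the difference of -0.16 without LPS has no probe position to set it against. For a hypothesis that the genomic region around Bid differs between the genotypes, 3 genes (Plxnd1, Depp1 and Clec4a2) of 110 tested within 100 protein-coding genes on each side differed at least 1.5-fold the same way in both conditions, and 41 of 947 other windows (4.33%, highest 4) held as many. An even spread of such genes would place 0.7 there. These 3 genes lie 50, 37 and 29 genes from Bid and 0 of its 10 nearest neighbours on each side did so, so no value speaks for a short flanking segment. The count goes with a difference of a wider region but does not decide it, and the hypothesis stays open.

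Ribosomal protein and oxidative phosphorylation genes were lower on the array labelled Bid–/– with LPS than on the WT LPS array. Both families lay below random lists matched on span and expression: those had medians from -0.38 to -0.12 against -0.52 for ribosomal protein genes, and from -0.29 to -0.04 against -0.71 for oxidative phosphorylation genes. The families were picked for their low values on this array, so they were likely to fall outside lists of other genes. The matching therefore cannot decide whether a trend with length is the whole cause. A length-dependent difference in RNA or labelling may be a part of the cause. Across the 11163 genes outside both families, rho with gene span was 0.385 with LPS and 0.134 without. With trends in intensity and gene span removed, the medians between labels with LPS were -0.35 for ribosomal protein and -0.645 for oxidative phosphorylation genes. Most of each difference thus remained after removal of the gene span trend, but span only stands in for length, so the whole cause stays undecided. Gene span is not transcript length, which was not used here. An LPS response that differs between the labels, with medians of 0.23 in WT and -0.225 on the arrays labelled Bid–/– for ribosomal protein genes and of 0.22 and -0.375 for oxidative phosphorylation genes, stays open and was not tested. The -0.225 lay within random lists matched on span and expression (-0.265 to -0.07). With trends in intensity and gene span removed, the ribosomal protein medians were 0.14 and -0.06. Those of oxidative phosphorylation genes were then 0.21 and -0.22.

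Fibroblast and mural genes were higher on the WT LPS array and on the control array labelled Bid–/– than on the WT control array. A genotype difference of equal size in both conditions is argued against by the median of 0.15 with LPS, and an LPS effect of equal size in both genotypes by the median of 0.015 on the arrays labelled Bid–/–, with the difference of response at percentile 0.0. These values are part of the pattern itself and no separate test. A larger share of fibroblast-like cells in those cultures may be a candidate source: 24 further fibroblast transcripts above the floor, on none of the lists and picked from general knowledge, had medians of 0.47 on the WT LPS array (22 above 0) and 0.285 on the control array labelled Bid–/– (17 above 0), both at percentile 100.0, and of -0.125 between labels with LPS (8 above 0, percentile 2.92). Both differences share the WT control array, and genes regulated together without any change in cell share would give the same values. An LPS response of these genes that depends on genotype stays open.

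Only Bid and the genes named for the highest or lowest values across all genes were searched, not list members or neighbours of Bid. Both values had to reach the median absolute difference of all genes: 0.26 for LPS in either label, 0.11 between labels without LPS and 0.22 with it. Beside Bid, those of opposite direction with LPS in the 2 labels were Timp1 (difference of response -2.98), Tagln (-2.09), Dcn (-2.02), S100a6 (-1.57), Ccn2 (-1.55) and Ppbp (-0.88). Of the other genes searched, those higher on the array labelled Bid–/– without LPS and lower with it were Rnu3a (-2.07), Sfrp4 (-1.86), Cxcl3 (-1.56), Cxcl1 (-1.24) and Il12b (-0.86). The reverse held for Phxr4 (1.56), Mir181b-1 (1.16), Mir125a (1.12), Snora30 (1.08), Mir181a-1 (1.06), Styx (1.05) and Slc40a1 (1.04). Rnu3a, Sfrp4 and Mir181a-1 reached the floor on a single array, so their differences between the control arrays lie below it.

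Among 2127 unnamed probe sets above the floor, 11 were at least 2-fold higher and 6 lower with LPS in both labels. Among 826 probe sets that name several genes, 1 was higher and 17 were lower; several of the 17 repeat the same values, which leaves 8 distinct sets of values.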

How the results depend on the processing

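The noise within the rounding and the removal of a gene span trend were chosen after seeing the data; the other alternatives were fixed before. Of the recomputed values for the main comparisons, 97 stayed within the main value's tolerance, 43 moved and 0 reversed. Counts, slopes and fit calls could only stay or move, so for them 0 reversed was fixed in advance. The share of higher genes between labels with LPS went from 40.0% to 53.4% after quantile normalization. In the other settings it lay between 37.4% and 44.0%. Among single genes, other lists and other comparisons of the response lists, 480 stayed, 36 moved and 2 lists lost their place outside the random lists. For list medians, a sign change counted as reversed only for a called value. That leaves out the cytokine and chemokine medians between the labels with LPS, which lay within the random lists and changed sign to 0.03 and 0.02 with both trends removed. The slope of the response labelled Bid–/– on the WT response stayed between 0.97 and 0.99.

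At a 1.5-fold threshold, genes higher and lower numbered 646 and 1231 for LPS in WT, 757 and 1141 for LPS on the arrays labelled Bid–/–, 158 and 48 between labels without LPS, 518 and 670 with LPS, and 369 and 686 for the difference of response, by construction. With the floor at the 75th percentile, which tests fewer genes, lower genes numbered 153 in WT, 113 on the arrays labelled Bid–/– and 5 between labels without LPS, and 10 genes had a higher LPS change on the arrays labelled Bid–/– than in WT. Removal of an intensity trend left 112 lower genes with LPS on the arrays labelled Bid–/– and gave 38 higher and 46 lower LPS changes there than in WT; with gene span as well there were 111 lower genes and 31 higher LPS changes. That last setting moved the median LPS difference of all genes on the arrays labelled Bid–/– by 0.10, and elsewhere shifts were smaller. The median difference of response of all genes moved by 0.077 with the intensity trend removed and by 0.067 with gene span as well. The cause of these moves was not tested.

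The additive limma fit for LPS called 1897 genes after quantile normalization, 823 with the floor at the 75th percentile, 876 without the genotype term, 0 without a floor, and 2184, 1941 and 1886 with noise within the rounding; each noise draw and quantile normalization kept all 367 of its calls. Breaking the exact ties raised the prior degrees of freedom from 3.07 to at least 7.06, which shows that ties lowered the count. For genotype it called 20 genes after quantile normalization and 26, 3 and 3 with noise, against 0.

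For the difference of response, the cytokine median was -0.33 with the intensity trend removed and -0.31 with gene span as well, the chemokine median -0.27 after quantile normalization, -0.28 and -0.23, NF-kB feedback 0.14 and 0.13, immediate early and MAPK feedback 0.094 with gene span, interferon-stimulated genes 0.37 after quantile normalization, 0.44 and 0.41, and inflammatory enzymes and effectors -0.062 and -0.076. These 6 lists kept their place inside or outside the random lists in the settings where it was recomputed: lists matched on response, lists limited to genes above the floor, and both trends removed. It was not recomputed for quantile normalization or the intensity trend alone. No array was left out in turn, since each is the only array of its group. Signal over background could not be set against these values, because probe-level background was not used here.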

Other observations

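Several lists not described above differed between arrays. Cell cycle genes had a median of -0.25 with LPS on the arrays labelled Bid–/– (percentile 0.02, 21 of 24 below 0), against 0.015 in WT (percentile 47.8, 12 below 0). They were 0.17 higher on the control array labelled Bid–/– than in WT, with the mitotic kinases Plk1 0.58 and Aurka 0.37 higher. In the additive limma fit 0 of 16 tested genes passed, and 2 rose and 4 fell when adjusted over the list alone. Of the Bcl-2 family 0 of 15 passed, or 2 up and 1 down when adjusted over the list alone, with Bcl2l11, which encodes Bim, at 0.79 in WT and 0.88 on the arrays labelled Bid–/– and Bmf at -0.57 and -0.98. Among death receptors and caspases 2 rose (Cflar, the caspase-8 inhibitor FLIP, 1.08 and 1.11; Tnfrsf1b, 0.85 and 0.83) and 1 fell (Casp2, -0.83 and -0.73) of 18, and 2 rose and 4 fell when adjusted over the list alone. Of 18 inflammasome and pattern receptor genes Nlrp3 alone rose (2 rose and 3 fell when adjusted over the list alone), and the list was 0.12 higher without and 0.28 higher with LPS on the arrays labelled Bid–/– (percentiles 99.4 and 99.2), with the peptidoglycan sensor Nod1 0.56 and 0.91 higher.

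Nlrc5, the class I transactivator, was 1.52 higher on the array labelled Bid–/– with LPS, while the MHC class I list had a median of 0.16 without and 0.01 with LPS. With trends in intensity and gene span removed these medians were 0.17 and 0.15. In the MHC class II and costimulation list Cd40 (2.03 and 1.76) and Cd80 (1.73 and 1.61) rose with LPS, 2 of 8 tested and 3 when adjusted over the list alone; its difference of response was -0.27 (percentile 0.74, and 3.58 with the gene span trend removed). In the phagocytosis and lysosome list 1 of 24 rose, Gpr84 (1.43 and 1.22), or 2 when adjusted over the list alone, and Trem2 read 8.18, 8.29, 8.34 and 7.43 on the WT control, WT LPS, and labelled Bid–/– control and LPS arrays. Cholesterol synthesis genes were lower on the array labelled Bid–/– with LPS (median -0.23, percentile 0.43), with Sc5d -0.93 and Fdps -0.67, and 0 of 15 passed in the LPS fit (2 fell when adjusted over the list alone). Heat shock and ER stress genes had LPS medians of 0.27 in WT and 0.09 on the arrays labelled Bid–/–, and 0 of 15 passed over all genes and over the list alone. With trends in intensity and gene span removed the medians were 0.23 and 0.26, so the gap between labels did not hold.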
